A study of Mus musculus with 12 samples.

How the data were processed

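Gene expression was measured by RNA-seq in 12 libraries from whole, pulverized small intestine of C57BL/6 mice, per the labels. The 4 groups were wild type (WT) neonates, NCoR1 intestinal knockout (KO) neonates, WT adults and KO adults, with 3 libraries per group. Neonates were 12 days old and adults 10 weeks old, per the labels, and each library was made from the pooled RNA of 2 mice, per the series design text. Stranded TruSeq mRNA libraries were run for 36 cycles on an Illumina HiSeq instrument, per the labels' protocols. The series design text names the strains F/FUN and DIECUN without explaining them. Which group each strain belongs to is not given in the sources used here, and groups were taken from the sample labels.

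Reads were aligned with Bowtie 0.12.2 to the mouse genome build mm9, per the submitters' processing notes. Reads in exons were counted per gene on the opposite strand with HOMER's analyzeRepeats program and condensed to 1 entry per gene, per the file headers. The version of HOMER and the handling of reads that match several places are not given in the sources used here. The authors deposited a table of all genes for each age, with 23333 genes for neonates and 23954 for adults, of which 23319 were in both by Entrez Gene identifier. Of the shared genes, 94.3% had the same exon length in both tables. In 25 gene symbols of the neonate table and 27 of the adult table a spreadsheet had turned the symbol into a date, so genes were matched by identifier. No entry lacked a gene.

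The columns deposited by the authors as reads hold a signal per gene, namely read counts divided by 1 factor per library so that every library of a table sums to the same total. Because the factor is fixed within a library, whole reads could be recovered: 100% of values in each library were whole multiples of 1 step within 0.01 deposited units, with a largest deviation of 0.0054. Recovered reads per library, in units of 1e+06, ranged from 8.44 to 9.34 in WT neonates, 5.93 to 8.31 in KO neonates, 9.78 to 11.8 in WT adults and 11.9 to 13.1 in KO adults. The deposited RPKM columns are scaled by exon length and by a library total larger than the reads in genes, and reads in genes made up 45.1% of that total in WT adults replicate 3 against 50.6% or more in the other libraries. The authors also deposited a log2 fold change and a false discovery rate (an adjusted p-value) per gene, from a test the headers do not name. By the values, the sign of that log2 fold change is KO minus WT in the neonate table and WT minus KO in the adult table. Their lists hold 1022 genes higher and 829 lower in KO neonates, and 1265 higher and 930 lower in KO adults with a false discovery rate of up to 0.0996. These lists served for checking signs and for no other result.

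Before the data were examined, the test for each comparison, 40 gene lists, the rule for named genes and a set of alternative settings were fixed. The plan named edgeR for raw counts and limma for normalized values. Since the deposited values were normalized, limma 3.58.1 was used in R 4.3.3, and count tests on the recovered reads served as alternatives. Deposited values were divided by the library's sum and multiplied by 1e+06 to give CPM. Genes with at least 1 CPM in at least 3 libraries were kept. Values were tested as log2(CPM + 1) with limma's trended and robust moderated test, KO against WT within each age, and called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are on that scale, which understates the change of low genes. This left 14215 genes in neonates and 13463 in adults. The difference of the KO effect between ages was tested on 14588 genes in a single limma fit of the 4 groups, as the effect in adults minus that in neonates. All p-values reflect the spread between pools of mice, not between single mice. WT adults were set beside WT neonates as values only, without a test, because the tables were scaled separately and age and table cannot be separated.

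Gene lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists. Camera sets the members against all other tested genes, so a called direction is relative to those genes and need not be a change from 0. Camera with an estimated correlation and fry were run beside it. For each list, the number of members passing is given over all genes tested and adjusted over the list alone. The named genes of each comparison are Ncor1; the 10 with the largest rise and the 10 with the largest fall among called genes with at least 5 CPM in the higher group and no overlap between the KO and WT libraries, leaving out provisional symbols; up to 4 members with the lowest adjusted p of each list that was called or had at least 3 called members; and 10 fixed genes (Ugt1a1, Cyp3a11, Cyp2b10, Sis, Lct, Fcgrt, Treh, Arg2, Mki67 and Cdkn1a). For the difference between ages, the rule takes the 5 genes with the largest difference in each direction. Some genes named by this rule are withheld for evaluation and not reported here. With no effect, 3 libraries against 3 fail to overlap in 10% of genes.

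Alternatives fixed beforehand were edgeR 4.0.16 with RLE factors and DESeq2 1.42.0 on the recovered reads, no filter, a pseudocount of 0.1, a minimum of 1.5-fold, all 12 libraries in a single fit, the replicate number as a block, an estimated correlation for lists, and leaving out each library. Settings added after seeing the data were limma and edgeR with TMM factors, deposited RPKM in place of CPM, and totals without Rn45s, Mir6236 and Lars2 or without the 50 most abundant genes. Adjusted p-values that DESeq2 left undefined stayed undefined.

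The limma, edgeR and DESeq2 tests were tested on simulated data with 200 genes changed, or 199 for the difference between ages. For the neonate comparison (14287 simulated genes) limma recovered 95% of 2-fold and 99% of 4-fold changes, with 6.28% of its calls false. For adults (13594 genes) it recovered 95% and 100%, with 9.3% of calls false, above the nominal rate. For the difference between ages (14673 genes) it recovered 87.9% and 97%, with 5.64% false. Camera, at the preset and at an estimated correlation, called 10 of 10 changed lists at each age. Of 30 unchanged lists it called 0 in neonates at both correlations, and in adults 2 at the preset and 0 at an estimated correlation. Simulated genes were drawn independently of each other, so these rates do not cover lists of correlated genes. In the real libraries, other splits called up to 19 lists at each age at the preset correlation. Fry and the list test of the difference were not tested on simulated data. Figures were drawn with matplotlib 3.10.9.

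Values of gene families with near-identical members are uncertain, since 36-cycle reads can match several of them: the Cyp3a, Cyp2c, Ces2, Gsta, Akr1, Ifit, Defa and Serpina1 families, and the Ugt1a genes, which share exons. Counting used strand, so antisense genes are separated as far as the library kit marks strand. Ncor1 values cover all counted exons and all cells of the tissue, and the deleted part was not measured apart. Coordinates are those of the deposited tables, build mm9.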

Results

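RNA-seq of whole small intestine compared wild type mice (WT) with mice lacking NCoR1 in the intestine (KO). NCoR1 is a corepressor that nuclear receptors recruit to keep their target genes silent. Tissue came from neonates of 12 days and adults of 10 weeks, and each of the 4 groups held 3 libraries, each a pool of 2 mice. Recovered reads in genes, in units of 1e+06, were 8.53, 9.34 and 8.44 in WT neonates, 7.91, 8.31 and 5.93 in KO neonates, 11.8, 11.3 and 9.78 in WT adults, and 12.4, 13.1 and 11.9 in KO adults. Levels are given as mean CPM ± SD over 3 libraries, computed from the deposited scaled reads, and differences as log2 of KO over WT.

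Ncor1 itself (Entrez Gene 20185, mm9 chromosome 11, 62129928 to 62252017) was measured first. In neonates it stood at 446.9, 459.3 and 451.4 CPM in WT and 244.9, 213.3 and 234.5 CPM in KO libraries. In adults it stood at 239.5, 252.2 and 244.7 CPM in WT and 159.3, 167.8 and 163.9 CPM in KO libraries. Each KO library lay below every WT library of its age. The log2 difference was -0.97 in neonates (SE 0.0563, limma adjusted p = 1.73e-10) and -0.58 in adults (SE 0.0735, limma adjusted p = 0.00021). The remaining reads may include those from undeleted exons and from cells outside the epithelium, which the tissue also holds. Their source was not measured.

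**Figure D1:**
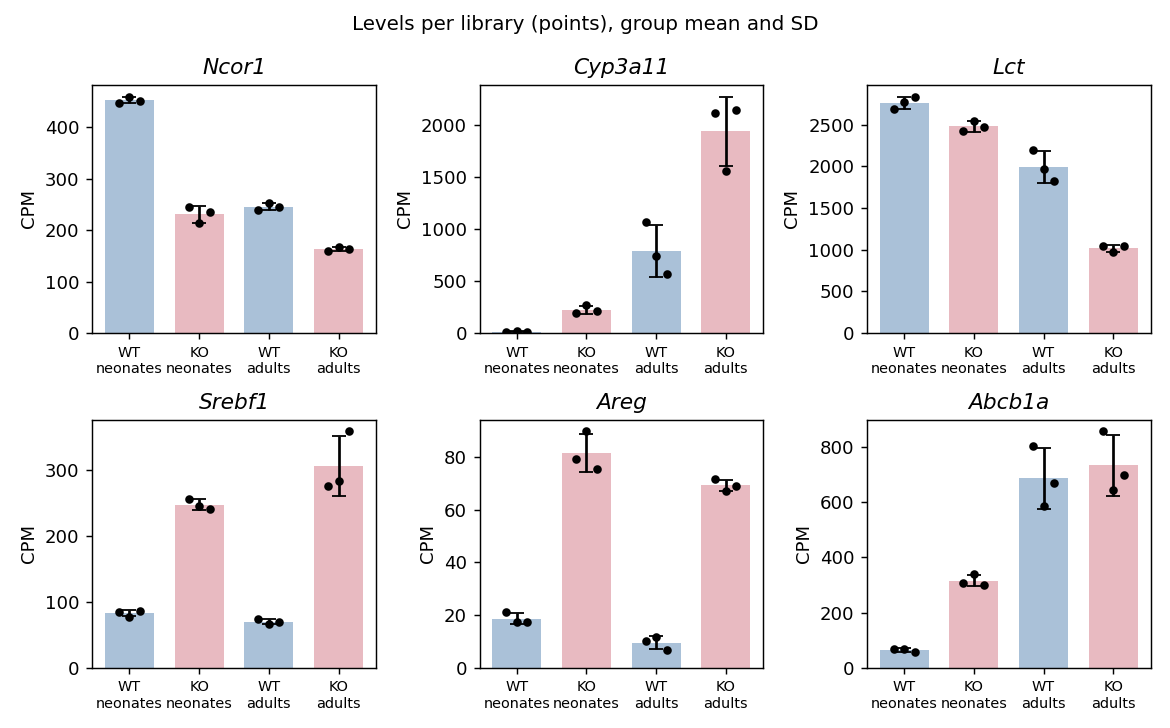
Levels of Ncor1, Cyp3a11, Lct, Srebf1, Areg and Abcb1a in CPM (y axis) in the 4 groups (x axis), with points for the 3 libraries, bars for their mean and whiskers for the SD. Ncor1 is lower in each KO library at both ages, Srebf1 and Areg are higher at both ages, and Abcb1a is higher in KO neonates.

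The comparison of KO with WT neonates asks how intestinal gene expression before weaning depends on NCoR1. Genes of drug metabolism and lipid handling were among those that rose. Cyp3a11, a drug-metabolizing cytochrome P450, rose from 13.8 ± 1.996 to 225.4 ± 37.6 CPM (16.3-fold), and Abcb1a, the P-glycoprotein efflux pump, from 64.4 ± 6.27 to 315.0 ± 20.4 CPM (4.89-fold). The largest rise was that of Hgd, an enzyme of tyrosine breakdown (Entrez Gene 15233, chromosome 16, 37580239 to 37632112), from 8.78 ± 0.719 to 157.4 ± 10.1 CPM (17.9-fold). The largest fall was that of Lrp2, the endocytic receptor megalin (Entrez Gene 14725, chromosome 2, 69262392 to 69424124), from 28.8 ± 1.63 to 2.69 ± 0.388 CPM.

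For the named genes with the largest changes in neonates, limma gave log2 differences of 4.02 for Hgd (SE 0.085, adjusted p = 1.24e-17), 3.93 for Cyp3a11 (SE 0.127, adjusted p = 2.15e-08), 2.28 for Abcb1a (SE 0.0711, adjusted p = 4.18e-14) and -3.02 for Lrp2 (SE 0.134, adjusted p = 2.78e-12). Other large rises were those of Cyp2c55 (3.80), Cyp2c66 (2.92), Akr1b7 (2.89), the cholesterol exporter Abca1 (2.71), Ubd (2.65) and Adh6a (2.29). Akp3, an intestinal alkaline phosphatase, rose from 14.5 ± 6.78 to 187.5 ± 88.4 CPM (limma adjusted p = 0.02), a call lost without WT neonates 2 (adjusted p = 0.075), WT neonates 3 (0.071), KO neonates 1 (0.0624) or KO neonates 2 (0.0712). Besides Lrp2, large falls were those of Igf2as (-2.49, named Igf2os in the adult table), the NADPH oxidase Nox4 (-2.39), Tmprss6 (-2.16), Ryr1 (-2.05), the antitrypsin gene Serpina1e (-1.95), the complement gene C8b (-1.90), Sucnr1 (-1.88) and Bmp8a (-1.86). Serpina1e fell from 250.7 ± 16.2 to 64.2 ± 5.71 CPM and Nox4 from 97.9 ± 23.8 to 17.9 ± 5.09 CPM.

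Drug metabolism rose as a group in KO neonates. All 14 tested genes of the 22 in the phase I list rose, also when adjusted over the list alone (camera adjusted p = 5.5e-32, and 0.0457 with an estimated correlation). The filter takes in a low gene that KO raises and leaves out a gene low in both groups, which favours rises in this count. Among them, Cyp2c65 rose from 26.3 ± 2.70 to 119.4 ± 8.62 CPM and Cyp3a25 from 62.1 ± 8.48 to 297.6 ± 20.2 CPM. Cyp2b10 rose from 0.622 ± 0.374 to 4.73 ± 1.46 CPM (limma adjusted p = 1.03e-05). Of 19 phase II conjugation genes, 13 rose and 2 fell, or 14 and 2 adjusted over the list alone (camera adjusted p = 7.08e-14, and 0.0457 with an estimated correlation). The sulfotransferase gene Sult1d1 rose from 282.1 ± 9.07 to 568.5 ± 32.4 CPM, and the glutathione transferase gene Gsta3 fell from 19.6 ± 1.67 to 6.70 ± 0.542 CPM. Ugt1a1, the bilirubin-conjugating enzyme, rose from 23.7 ± 0.944 to 39.2 ± 2.06 CPM (limma adjusted p = 6.39e-06), with the limit that Ugt1a genes share exons. Of 4 efflux transporters 2 rose, or 4 adjusted over the list alone (camera adjusted p = 2.33e-07), a list call with an adjusted p = 0.0688 with an estimated correlation. The 2 were Abcb1a and Abcg2, the latter rising from 239.9 ± 9.46 to 284.9 ± 14.1 CPM.

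Fatty acid oxidation genes and LXR targets rose too, and cholesterol synthesis genes did not as a group. Of 24 PPAR-alpha targets and fatty acid oxidation genes, 20 rose and 1 fell, or 21 and 1 adjusted over the list alone (camera adjusted p = 7.06e-29, and 0.0457 with an estimated correlation). Pdk4, a kinase that restrains glucose oxidation, rose from 123.7 ± 10.8 to 342.2 ± 14.9 CPM, Ehhadh from 203.2 ± 5.40 to 464.6 ± 44.3 CPM, and the fatty acid binding protein gene Fabp1 from 1841 ± 175 to 3317 ± 122 CPM. Of 11 LXR targets 6 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 6.26e-13, and 0.0457 with an estimated correlation). The sterol transporter genes Abcg5 and Abcg8 rose from 256.3 ± 10.1 to 561.4 ± 4.90 CPM and from 262.6 ± 15.7 to 589.1 ± 17.3 CPM, and Srebf1, a regulator of fatty acid synthesis, from 82.7 ± 4.66 to 247.8 ± 7.96 CPM (limma adjusted p = 2.91e-13). Of 13 lipid absorption and lipoprotein genes 8 were higher and 1 lower, with the same counts adjusted over the list alone, and 10 and none with TMM factors (camera adjusted p = 4.41e-08, and 0.0457 with an estimated correlation). The apolipoprotein gene Apob rose from 15230 ± 542 to 23630 ± 1446 CPM. Of 17 cholesterol synthesis genes 1 was higher and 3 lower, with the same counts adjusted over the list alone, and 1 and 1 with TMM factors (camera adjusted p = 0.501). Without WT neonates 1, WT neonates 2 or KO neonates 1, cholesterol synthesis had 2 called genes, both lower.

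Brush border genes rose in KO neonates, 11 of 12, with the same count adjusted over the list alone (camera adjusted p = 8.46e-14, and 0.0457 with an estimated correlation). Among them Enpep rose from 448.4 ± 12.7 to 687.6 ± 7.89 CPM and the glucose transporter gene Slc5a1 from 694.5 ± 29.0 to 991.5 ± 104 CPM. Of 7 genes of adult-type enterocytes that come on at weaning, 2 rose, or 3 adjusted over the list alone (camera adjusted p = 6.27e-06, and adjusted p = 0.142 with an estimated correlation). The disaccharidase gene Mgam rose from 243.0 ± 14.1 to 343.2 ± 4.30 CPM, and sucrase-isomaltase, Sis, stood at 31.9 ± 9.13 and 94.2 ± 32.1 CPM (limma adjusted p = 0.0504, or 0.0485 with TMM factors). Treh stood at 12.3 ± 1.78 and 13.8 ± 3.64 CPM and Arg2 at 8.50 ± 3.82 and 23.3 ± 8.65 CPM, neither called. Of 12 suckling-type enterocyte genes 2 were higher and 4 lower, or 2 and 7 adjusted over the list alone, and 2 and 3 with TMM factors (camera adjusted p = 0.224). Fry, which tests members against no change, called this list lower (fry adjusted p = 0.00223). Its median log2 difference was -0.136, or -0.0331 with TMM factors. Lrp2, Nox4 and the galactosidase gene Glb1 (402.6 ± 17.6 to 268.3 ± 13.3 CPM) fell, while Cubn rose from 891.8 ± 33.4 to 1179 ± 72.7 CPM. Lct, the lactase gene, stood at 2760 ± 73.0 and 2479 ± 64.0 CPM (limma adjusted p = 0.0189), a call that ended with TMM factors (0.594) and without WT neonates 2 (0.0614), WT neonates 3 (0.0931), KO neonates 1 (0.0584) or KO neonates 3 (0.0649). Fcgrt, the neonatal Fc receptor gene, stood at 4664 ± 177 and 4833 ± 201 CPM (limma adjusted p = 0.477). The adult-type list had 1 called gene without WT neonates 2, WT neonates 3, KO neonates 1 or KO neonates 2.

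Of 14 interferon response genes 7 rose in KO neonates, or 8 with 1 lower adjusted over the list alone (camera adjusted p = 7.44e-08, and adjusted p = 0.305 with an estimated correlation). Ifit2 rose from 252.3 ± 38.0 to 936.1 ± 43.3 CPM. All 3 vitamin D targets rose, also adjusted over the list alone (camera adjusted p = 9.68e-07, and adjusted p = 0.0647 with an estimated correlation). The calcium-binding protein gene S100g rose from 124.1 ± 22.5 to 416.5 ± 20.0 CPM. Of 4 FXR targets and bile acid transport genes 3 rose, or 4 adjusted over the list alone (camera adjusted p = 1.63e-05, and adjusted p = 0.142 with an estimated correlation). Of these, Fgf15 rose from 42.7 ± 7.73 to 94.6 ± 16.8 CPM (limma adjusted p = 0.00976). Without WT neonates 2 the calls of all 3, Fgf15 (limma adjusted p = 0.0686), Nr0b2 (adjusted p = 0.151) and Slc10a2 (adjusted p = 0.16), were lost and Fabp6 alone was called. Without KO neonates 1 or KO neonates 3 the list had 1 called gene. Retinoid metabolism genes went both ways, with 3 of 7 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.0157, and adjusted p = 0.315 with an estimated correlation). Dhrs3 rose from 74.0 ± 3.45 to 108.4 ± 9.95 CPM and Lrat fell from 263.9 ± 25.3 to 178.2 ± 3.46 CPM. Thyroid hormone targets, with Me1 the only called gene of 4 (the same adjusted over the list alone), had a camera adjusted p = 0.0111, and adjusted p = 0.146 with an estimated correlation. Me1 rose from 42.2 ± 6.19 to 94.9 ± 10.4 CPM. Iron handling (2 of 5 higher, the same adjusted over the list alone) had a camera adjusted p = 0.0296, and adjusted p = 0.267 with an estimated correlation. Both its calls, Heph (limma adjusted p = 0.0641) and Slc40a1 (adjusted p = 0.121), were lost without WT neonates 2, and 1 gene was called without WT neonates 1, WT neonates 3 or KO neonates 1. In the corepressor complex list Tbl1xr1 rose from 102.9 ± 9.26 to 170.1 ± 5.27 CPM and Tbl1x from 42.8 ± 4.29 to 58.4 ± 7.22 CPM, and Ncor1 was among the 2 lower genes of the 6 (1 with TMM factors), with the same counts adjusted over the list alone (camera adjusted p = 0.41). Of 18 nuclear receptor genes 5 were higher and 2 lower, the same adjusted over the list alone, and 6 and 1 with TMM factors (camera adjusted p = 0.0837), Ppara among them from 46.8 ± 5.08 to 93.2 ± 13.4 CPM.

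Markers of proliferation and of cells outside the absorptive lineage gave few called genes in neonates. Of 24 proliferation genes 1 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.0238, and adjusted p = 0.434 with an estimated correlation). This camera call was toward higher levels relative to the other tested genes. Mki67 stood at 253.0 ± 10.3 and 240.5 ± 9.27 CPM (limma adjusted p = 0.379). Of 7 fibroblast genes 3 were lower, or 4 adjusted over the list alone (camera adjusted p = 0.0308, and adjusted p = 0.607 with an estimated correlation), and with TMM factors no fibroblast gene was called. Of 8 myeloid genes 4 were lower, or 5 adjusted over the list alone, and 1 with TMM factors (camera adjusted p = 0.42), with Csf1r falling from 226.0 ± 29.6 to 141.4 ± 17.9 CPM. Lower genes numbered 3 of 13 in the enteroendocrine list (Gip from 60.0 ± 4.67 to 33.9 ± 7.24 CPM) and 2 each in the stem cell, MHC class II, and enteric neuron and glia lists, with the same counts adjusted over the lists alone and no camera call. In the Paneth list 1 of 12 genes was higher (none adjusted over the list alone) and in the liver list 1 rose and 1 fell of 3 (1 and 2 adjusted over the list alone), again with no camera call. Clock genes (1 higher and 3 lower of 15; 1 and 4 adjusted over the list alone), p53 targets (3 and 2 of 13), oxidative stress genes (1 and 2 of 9) and antimicrobial genes (2 and 1 of 10) also had none, with the last 3 counts unchanged when adjusted over the list alone. With TMM factors these lists had 2 and 1, 4 and 1, 3 and 2, and 2 higher and none lower, and the enteroendocrine list 1 and 1. In the remaining 9 lists (goblet, tuft, smooth muscle, endothelium, T cell, B and plasma cell, pancreas, red blood cell and adipocyte), limma called 0 of 60 genes, with 6 at an unadjusted p under 0.05. With TMM factors limma called 3 of these 60 genes and edgeR 2. Cdkn1a stood at 55.9 ± 4.07 and 57.2 ± 12.8 CPM (limma adjusted p = 0.963). Omitting 1 library moved several of these counts. Without WT neonates 2 no fibroblast gene was called, and 1 was without KO neonates 1 or KO neonates 3. Myeloid genes numbered 1 without WT neonates 1, WT neonates 2 or KO neonates 3, and 2 without KO neonates 2. Neuron and glia genes numbered 1 without any 1 of the WT neonates or KO neonates 3, and MHC class II genes 4 without KO neonates 1. Proliferation had 1 called gene, lower, without WT neonates 2, WT neonates 3, KO neonates 1 or KO neonates 2, and the Paneth list none without WT neonates 1 or WT neonates 2 and 3 without KO neonates 2. Antimicrobial genes numbered 1 without WT neonates 2 or KO neonates 2, clock genes 1 without KO neonates 3, and p53 targets 3 without WT neonates 3 or KO neonates 1.

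In all, limma called 3009 of 14215 genes in neonates, 741 higher and 2268 lower in KO. This split follows the deposited scaling: the median log2 difference over tested genes was -0.11, and with TMM factors it was -0.02 with 1278 genes higher and 1098 lower. The number of lower genes without WT neonates 2 was 1426, and DESeq2 on the recovered reads called 1526 genes, 983 higher and 543 lower. Camera at the preset correlation called 16 of 39 lists, 15 toward higher and 1, the fibroblast list, toward lower levels relative to the other genes. It called 6 of them also with an estimated correlation, and gave up to 19 lists in other splits of the same 6 libraries. Fry called 13 lists.

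**Figure D2:**
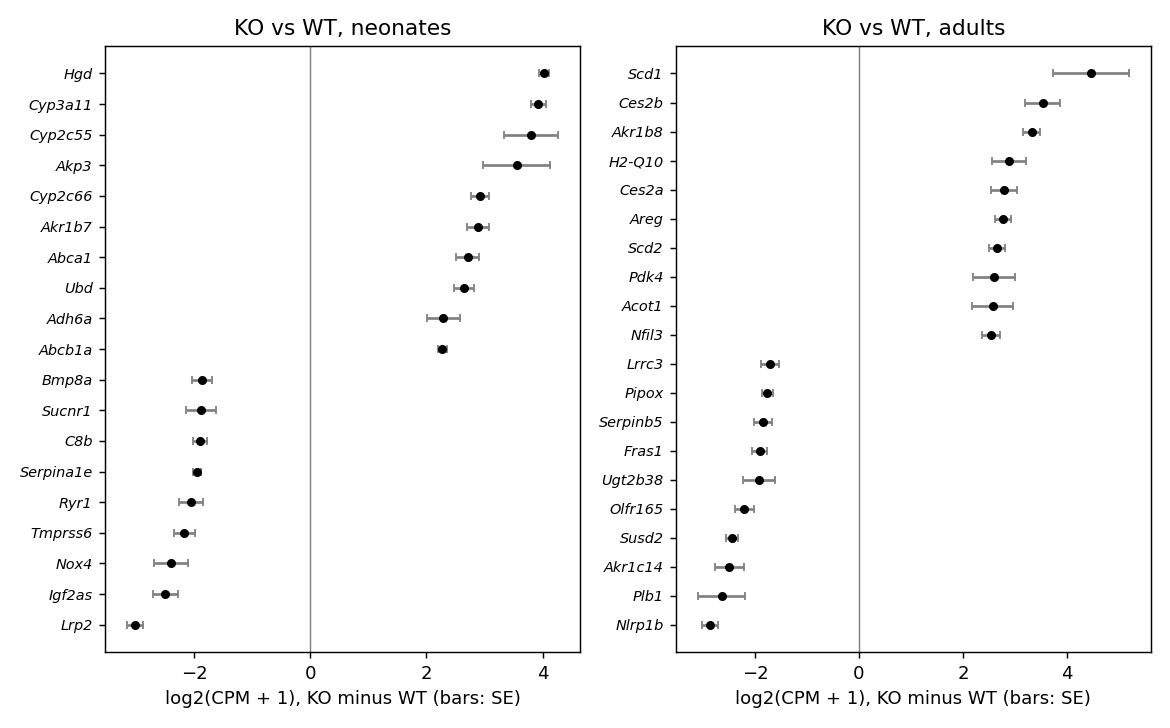
Log2 difference of KO minus WT (x axis, points, with the SE as bars) for the named genes with the largest rises and falls per age (y axis), 3 libraries per group. Hgd at 4.02 and Lrp2 at -3.02 bound the neonates, and Scd1 at 4.47 and Nlrp1b at -2.87 the adults.

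The comparison of KO with WT adults asks the same of the mature intestine. Lipid-synthesis and fatty acid genes were among those that rose. Scd2, a fatty acid desaturase gene, rose from 178.2 ± 21.7 to 1139 ± 219 CPM (6.39-fold), and Srebf1 (Entrez Gene 20787, chromosome 11, 60012591 to 60034106) from 70.0 ± 3.86 to 306.1 ± 45.6 CPM (4.37-fold). Areg, a growth factor of the EGF family (Entrez Gene 11839, chromosome 5, 91568641 to 91577458), rose from 9.50 ± 2.43 to 69.2 ± 2.17 CPM (7.28-fold). The largest fall was that of the inflammasome sensor gene Nlrp1b (Entrez Gene 637515, chromosome 11, 70966604 to 71014958), from 10.6 ± 1.11 to 0.587 ± 0.074 CPM.

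For the named genes with the largest changes in adults, limma gave log2 differences of 2.66 for Scd2 (SE 0.149, adjusted p = 1.54e-05), 2.10 for Srebf1 (SE 0.1, adjusted p = 1.08e-07), 2.77 for Areg (SE 0.151, adjusted p = 2.82e-06), 3.32 for Akr1b8 (SE 0.168, adjusted p = 9.29e-06) and -2.87 for Nlrp1b (SE 0.155, adjusted p = 2.57e-07). Scd1, another desaturase gene, had the largest difference, 4.47, between 96.2 ± 88.5 and 1699 ± 492 CPM (limma adjusted p = 0.0239). Its call held without WT adults 1 and ended without WT adults 2 (0.0775), WT adults 3 (0.0644), KO adults 1 (0.0653), KO adults 2 (0.0785) or KO adults 3 (0.0995). Further large rises were those of the carboxylesterase genes Ces2b (3.53) and Ces2a (2.79), H2-Q10 (2.89) and Nfil3 (2.54), a repressor tied to the clock. Pdk4 (2.60) and Acot1 (2.57) rose as well (limma adjusted p = 0.02 and 0.00879), calls lost without WT adults 1 (0.0567 and 0.0587) or WT adults 2 (0.0609 and 0.0625). Besides Nlrp1b, large falls were those of Akr1c14 (-2.49), Susd2 (-2.44), Olfr165 (-2.20), Ugt2b38 (-1.92), Fras1 (-1.91), Serpinb5 (-1.84), Pipox (-1.76) and Lrrc3 (-1.71). Susd2 fell from 161.5 ± 30.5 to 28.5 ± 0.344 CPM. Plb1 (-2.64, limma adjusted p = 0.0267) kept its call without KO adults 3 and lost it without WT adults 1 (0.0654), WT adults 2 (0.0761), WT adults 3 (0.0652), KO adults 1 (0.0697) or KO adults 2 (0.0731).

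In KO adults 17 of 24 PPAR-alpha targets and fatty acid oxidation genes rose, or 21 adjusted over the list alone (camera adjusted p = 7.08e-27, and adjusted p = 0.16 with an estimated correlation). The carnitine carrier gene Slc25a20 rose from 48.9 ± 2.35 to 149.8 ± 3.93 CPM, Vnn1 from 109.8 ± 5.54 to 257.9 ± 12.5 CPM and Plin2, a lipid droplet coat gene, from 56.4 ± 0.642 to 126.9 ± 16.5 CPM. Of 11 LXR targets 8 rose and 2 fell, or 9 and 2 adjusted over the list alone (camera adjusted p = 2.29e-09, and adjusted p = 0.16 with an estimated correlation), Abcg8 from 208.6 ± 4.79 to 387.7 ± 27.6 CPM. Of 17 cholesterol synthesis genes 7 rose, or 10 adjusted over the list alone (camera adjusted p = 2.29e-09, and adjusted p = 0.47 with an estimated correlation). Insig1 rose from 79.3 ± 11.02 to 174.2 ± 16.0 CPM. Of 13 lipid absorption and lipoprotein genes 3 were higher and 1 lower, or 4 and 1 adjusted over the list alone, and 4 and none with TMM factors (camera adjusted p = 0.0829). All 4 calls, Apoc2 (limma adjusted p = 0.0814), Apoc3 (adjusted p = 0.0733), Apoa1 (adjusted p = 0.101) and Apob (adjusted p = 0.0795), were lost without KO adults 3. The list had 1 called gene without KO adults 2 and 2 without WT adults 1, WT adults 2 or KO adults 1. Cholesterol synthesis had 3 without WT adults 1 or KO adults 3, 4 without KO adults 2 and 11 without KO adults 1.

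Drug metabolism rose in part in KO adults. Of 17 phase I genes 7 were higher and 1 lower, or 8 and 2 adjusted over the list alone, and 7 and none with TMM factors (camera adjusted p = 1.52e-08, and adjusted p = 0.47 with an estimated correlation). Ces2c rose from 131.2 ± 19.8 to 384.2 ± 62.5 CPM and Cyp3a25 from 236.2 ± 44.5 to 632.3 ± 82.4 CPM. Por, the electron donor of cytochromes P450, rose from 303.8 ± 39.98 to 545.5 ± 56.3 CPM. Cyp3a11 rose from 792.5 ± 253 to 1944 ± 331 CPM (limma adjusted p = 0.0293), a call lost without WT adults 2 (0.104), KO adults 1 (0.0631) or KO adults 3 (0.0995). Cyp2b10 stood at 444.3 ± 103 and 237.0 ± 49.3 CPM (limma adjusted p = 0.0611) and Ugt1a1 at 91.8 ± 23.6 and 100.5 ± 36.1 CPM (limma adjusted p = 0.874). Of 19 phase II genes 4 were higher and 2 lower, the same adjusted over the list alone, and 4 and none with TMM factors (camera adjusted p = 0.0107, and adjusted p = 0.591 with an estimated correlation). Gstm3 rose from 149.7 ± 8.44 to 337.0 ± 80.4 CPM. Of 9 oxidative stress genes 5 rose, the same adjusted over the list alone (camera adjusted p = 5.06e-05, and adjusted p = 0.16 with an estimated correlation), with Gclm, a subunit of the first enzyme of glutathione synthesis, rising from 152.7 ± 13.3 to 232.6 ± 2.55 CPM. Of 6 FXR targets 2 rose, or 3 adjusted over the list alone (camera adjusted p = 0.00848, and adjusted p = 0.47 with an estimated correlation). The FXR-induced repressor gene Nr0b2 rose from 1.58 ± 0.177 to 9.82 ± 2.90 CPM. Without WT adults 2, KO adults 1 or KO adults 3 the phase I list had 5 called genes, and without WT adults 2 the phase II list had 3. The oxidative stress list had 2 without KO adults 2 or KO adults 3 and 3 without WT adults 1 or WT adults 2.

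Digestive enterocyte genes did not rise as a group in adults. Lct fell from 1994 ± 190 to 1017 ± 42.7 CPM (limma log2 difference -0.97, SE 0.0917, adjusted p = 2.24e-05), and Amn from 131.8 ± 21.4 to 63.5 ± 5.99 CPM, while Fcgrt rose from 55.6 ± 1.97 to 101.9 ± 10.1 CPM (limma adjusted p = 4.52e-05). These belong to the suckling-type list, in which 1 of 9 genes rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.625). Of 7 adult-type genes 3 were lower, the same adjusted over the list alone, and 1 with TMM factors (camera adjusted p = 0.181). The glucose transporter gene Slc2a2 fell from 557.0 ± 89.9 to 303.5 ± 6.06 CPM. Arg2 stood at 752.7 ± 54.6 and 568.3 ± 44.1 CPM (limma adjusted p = 0.0074, and 0.0542 with TMM factors), and Sis at 7638 ± 149 and 6547 ± 719 CPM (limma adjusted p = 0.132). Treh stood at 334.5 ± 52.6 and 255.5 ± 11.6 CPM (limma adjusted p = 0.0218), a call that ended with TMM factors (0.142) and without WT adults 1 (0.0778), KO adults 1 (0.0693), KO adults 2 (0.0696) or KO adults 3 (0.0532). Of 12 brush border genes 2 were lower, the same adjusted over the list alone (camera adjusted p = 0.296), among them the peptide transporter gene Slc15a1 at 1371 ± 118 and 954.6 ± 31.6 CPM.

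Clock genes went both ways in KO adults, with 4 of 16 higher and 2 lower, the same adjusted over the list alone, and 5 and 1 with TMM factors (camera adjusted p = 0.0259, and adjusted p = 0.47 with an estimated correlation). Arntl rose from 11.3 ± 2.43 to 36.6 ± 1.05 CPM, Npas2 from 36.9 ± 5.55 to 72.7 ± 8.43 CPM and Nr1d1 from 195.6 ± 37.3 to 377.1 ± 8.94 CPM. The time of day of tissue collection is not given in the sources used here. In the corepressor complex list 3 of 6 rose and 1 fell, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.0414, and adjusted p = 0.47 with an estimated correlation). Tbl1xr1 rose from 140.3 ± 6.69 to 305.9 ± 14.4 CPM. Of 5 thyroid hormone targets 2 rose, or 3 adjusted over the list alone (camera adjusted p = 0.0117, and adjusted p = 0.397 with an estimated correlation). Me1, in that list, rose from 78.7 ± 24.1 to 310.2 ± 72.0 CPM (limma adjusted p = 0.0124, and 0.0559 without KO adults 3). Of 12 p53 targets 2 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0117, and adjusted p = 0.47 with an estimated correlation). Cdkn1a stood at 256.0 ± 17.3 and 314.9 ± 34.7 CPM (limma adjusted p = 0.0401), a call lost without WT adults 1 (0.131), WT adults 2 (0.0946), KO adults 2 (0.0665) or KO adults 3 (0.192). Of 18 nuclear receptor genes 5 were higher and 5 lower, or 6 and 5 adjusted over the list alone, and 6 and 2 with TMM factors (camera adjusted p = 0.0744), with Ppara rising from 117.5 ± 18.6 to 266.2 ± 41.5 CPM and Pparg falling from 23.6 ± 3.02 to 12.5 ± 2.40 CPM. Retinoid metabolism (2 higher and 1 lower of 7) and vitamin D targets (1 higher of 3) had the same counts adjusted over the list alone and no camera call. Without KO adults 3 no thyroid hormone target was called. Without KO adults 2 the p53 list had 1 called gene, lower, and the nuclear receptor list 4 higher and 2 lower. No vitamin D target was called without WT adults 1, WT adults 3, KO adults 1 or KO adults 3.

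Part of the markers of secretory cells and of the stroma fell in KO adults. Of 12 Paneth cell genes 5 fell, the same adjusted over the list alone (camera adjusted p = 0.00211, and adjusted p = 0.47 with an estimated correlation). Lyz1 fell from 2565 ± 212 to 1585 ± 315 CPM and Itln1 from 1865 ± 232 to 1152 ± 200 CPM. Of 7 fibroblast genes 3 fell, or 6 adjusted over the list alone (camera adjusted p = 0.0117, and adjusted p = 0.47 with an estimated correlation). Dcn fell from 141.1 ± 17.2 to 93.9 ± 10.2 CPM. Goblet cells (3 of 10 lower, 2 with TMM factors, Zg16 from 2662 ± 278 to 1868 ± 235 CPM) had no camera call. Enteroendocrine cells (3 of 13 lower, 2 with TMM factors, Gip from 41.8 ± 3.79 to 25.0 ± 1.502 CPM) had none either. Adjusted over the list alone, these counts were 3 and 4. Of 8 T cell genes 2 rose, the same adjusted over the list alone (camera adjusted p = 0.00224, and adjusted p = 0.47 with an estimated correlation). The granzyme gene Gzma rose from 46.3 ± 4.06 to 66.4 ± 6.71 CPM. Antimicrobial genes, with 1 of 13 higher (none adjusted over the list alone), had a camera adjusted p = 0.0348, and adjusted p = 0.47 with an estimated correlation. Lower genes numbered 2 of 8 in the stem cell and in the smooth muscle list and 1 in the interferon, the neuron and glia and the liver lists, with no camera call. Adjusted over the list alone, they numbered 2 (with 1 higher) and 2, then 1, 3 and 1, and with TMM factors no smooth muscle gene was called. In the remaining 11 lists (efflux transporters, proliferation, MHC class II, iron handling, tuft, endothelium, B and plasma cell, myeloid, pancreas, red blood cell and adipocyte), limma called 0 of 87 genes, with 9 at an unadjusted p under 0.05. With TMM factors limma called 4 of these 87 genes and edgeR 2. The pancreas list among these had a median log2 difference of -1.43, or -1.31 with TMM factors (camera adjusted p = 0.0506), and of -0.60 in neonates. These acinar genes lay lower in KO beside these markers, without a call. Mki67 stood at 213.9 ± 37.3 and 171.1 ± 14.5 CPM (limma adjusted p = 0.0779). Omitting 1 library moved several of these counts, with 8 Paneth genes lower without WT adults 1, 5 fibroblast genes without WT adults 3 and 1 T cell gene higher without WT adults 2. Antimicrobial genes numbered 2 without WT adults 1 and none without WT adults 2 or WT adults 3. Neuron and glia genes numbered none without WT adults 2 or KO adults 3 and 2 without KO adults 1, and smooth muscle genes none without KO adults 3 and 1 without WT adults 2, WT adults 3 or KO adults 2. The stem cell list had 1 called gene without WT adults 2, KO adults 2 or KO adults 3, the interferon list 2 without WT adults 3 or KO adults 2, and the liver list none without KO adults 2.

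In all, limma called 2611 of 13463 genes in adults, 741 higher and 1870 lower in KO, with a median log2 difference of -0.11, while with TMM factors the median was -0.00324 with 1334 genes higher and 854 lower. The total fell to 1281 without KO adults 3 (437 higher, 844 lower), 1483 without WT adults 2 (954 lower) and 1605 without KO adults 2 (1085 lower), and limma on the deposited RPKM called 1167. Camera at the preset correlation called 15 of 40 lists and up to 19 in other splits of the same 6 libraries. Of the 15, 13 were toward higher and 2, the Paneth and fibroblast lists, toward lower levels relative to the other genes. With an estimated correlation it called 0, with 4 at an unadjusted p under 0.05, and fry called 6.

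**Figure D3:**
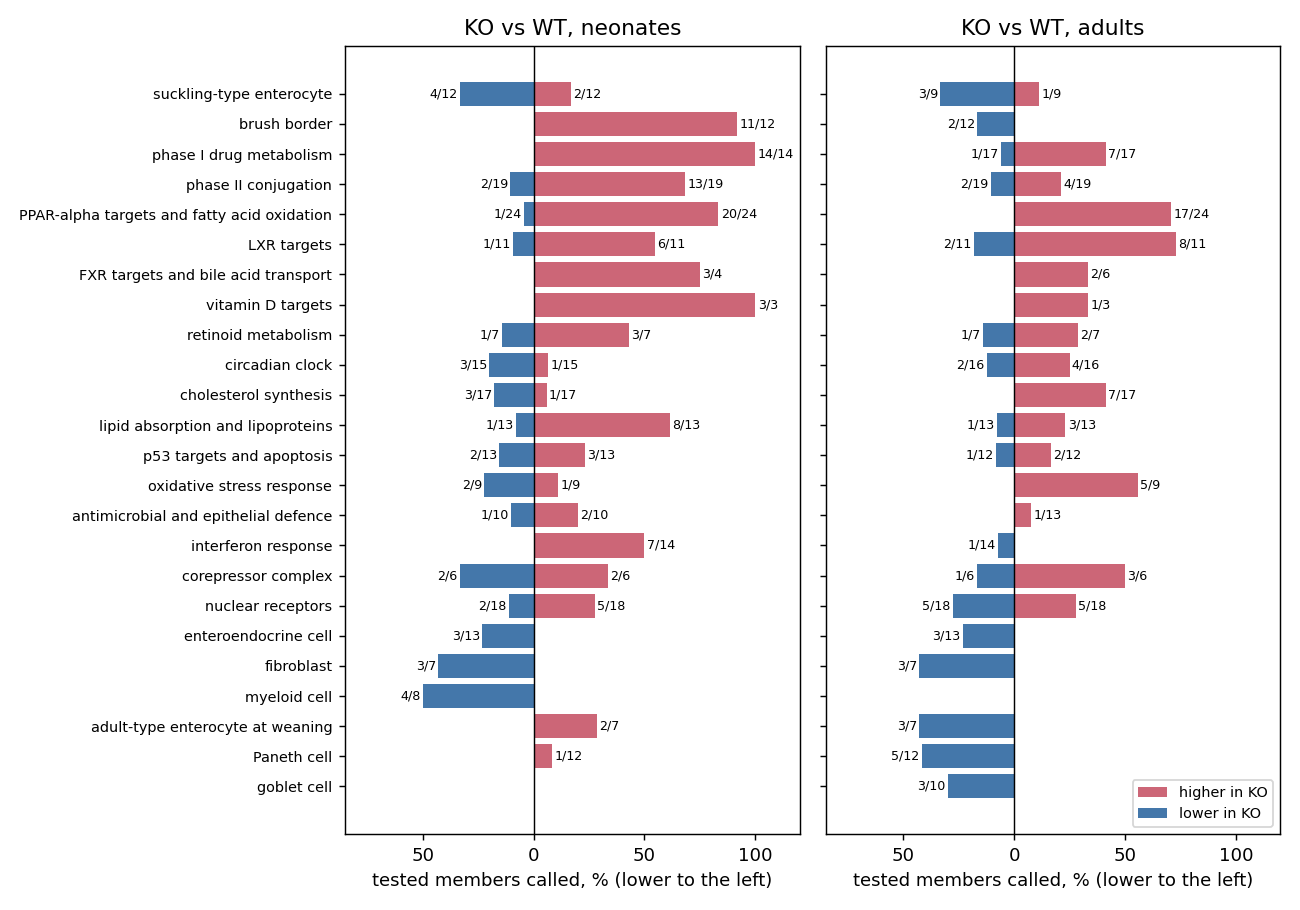
Percent of tested list members called higher (right) or lower (left) in KO (x axis) for the 24 lists (y axis) with at least 3 called members at either age, with bars for neonates and adults. The phase I list reaches 14 of 14 in neonates and 7 of 17 in adults, and cholesterol synthesis genes are higher in adults, 7 of 17, against 1 of 17 in neonates.

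The test of the difference between ages asks which genes respond to the loss of NCoR1 differently before and after weaning. Brush border and drug metabolism genes had a lower KO effect in adults than in neonates, and cholesterol synthesis, clock and PPAR-alpha genes a higher one, by camera at the preset correlation. None of these list calls held with an estimated correlation, and a minority of the phase I, cholesterol synthesis, clock and PPAR-alpha genes passed singly. The KO effect on Abcb1a was 2.18 lower on the log2 scale in adults (difference -2.18, SE 0.174, limma adjusted p = 1.78e-05) and that on Cyp3a11 2.60 lower (difference -2.60, SE 0.342, limma adjusted p = 0.00343). That on Nfil3 was 2.12 higher (SE 0.214, limma adjusted p = 4.14e-06), on Arntl 1.57 higher (SE 0.176, limma adjusted p = 1.66e-05) and on Slc25a20 1.02 higher (SE 0.0997, limma adjusted p = 3.47e-06). The decrease of Ncor1 was smaller in adults by 0.39 (limma adjusted p = 0.0128). Whether this bears on smaller effects of other genes in adults was not tested. Each age also has its own table, so age and table cannot be separated in this test either.

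The 5 largest differences toward higher effects in adults were those of Lrp2 (2.91), Ces2b (2.29), Ryr1 (2.20), Tmprss6 (2.17) and Serpina1e (2.16). The 5 toward lower effects were those of Hgd (-3.88), Cyp2b10 (-2.72), Plb1 (-2.68), Cyp3a11 (-2.60) and Nlrp1b (-2.49). Hgd, Lrp2, Ryr1, Tmprss6 and Serpina1e stood at about 1 CPM or less in adults of both genotypes, for Hgd at 0.149 ± 0.0920 and 0.267 ± 0.0344 CPM. At that level a fall in adults is barely detectable on the log2(CPM + 1) scale, which limits the comparison for Lrp2, Ryr1, Tmprss6 and Serpina1e, and likewise for Plb1 in neonates, at 0.643 and 0.708 CPM. A rise from such a level can be detected, as for Cyp2b10 in neonates. Nlrp1b was also low in WT neonates, at 1.29, 1.61 and 4.5 CPM, which limits how far it could fall there. The call for Ces2b (limma adjusted p = 0.0282) was lost without WT neonates 1 (0.0749), WT neonates 2 (0.0817), WT adults 1 (0.0654), WT adults 3 (0.0514) or KO adults 3 (0.058).

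By list, 8 of 12 brush border genes had a lower KO effect in adults, or 9 adjusted over the list alone (camera adjusted p = 7.38e-10, and adjusted p = 0.132 with an estimated correlation), among them Slc15a1 (-0.96) and Enpep (-0.76). Phase I genes (6 of 17 lower and 1 higher, or 9 and 1 adjusted over the list alone) had a camera adjusted p = 1.47e-06, and adjusted p = 0.375 with an estimated correlation. Of 17 cholesterol synthesis genes 6 had a higher effect in adults, or 14 adjusted over the list alone (camera adjusted p = 7.38e-10, and adjusted p = 0.287 with an estimated correlation), among them Insig1 (0.81). PPAR-alpha targets (6 of 24 higher, or 9 with 1 lower adjusted over the list alone; camera adjusted p = 7.28e-09, and adjusted p = 0.287 with an estimated correlation) and clock genes (4 of 16 higher, or 6 adjusted over the list alone; camera adjusted p = 0.0117, and adjusted p = 0.375 with an estimated correlation) followed. For 40 lists camera called 13, and 0 with an estimated correlation (6 at an unadjusted p under 0.05, 7 by fry), and other splits of the libraries within the ages gave up to 24.

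In all, limma called 796 of 14588 genes for the difference, 440 with a higher and 356 with a lower effect in adults, and 763 with TMM factors. The total was 517 without WT neonates 2 (284 higher, 233 lower) and 529 without KO adults 3 (293 and 236). Higher genes numbered 285 without WT neonates 1 and 281 without KO neonates 3, and lower genes 228 without WT neonates 3 and 226 without KO neonates 1.

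Many genes changed alike at both ages. Among 13103 genes tested at both, 280 rose at both ages against 40.4 for independent lists, and 677 fell at both against 299.6, while 27 rose in neonates and fell in adults and 31 did the reverse. With TMM factors 536 rose at both ages against 126 for independent lists and 221 fell at both against 63.4. The numbers that rose and fell at both were 532 and 224 with edgeR and TMM factors, 469 and 112 with DESeq2, and 178 and 186 with deposited RPKM. Genes lower at both ages numbered 386 without KO adults 3 and 411 without WT adults 2. Those with opposite calls, 58 with all libraries, numbered 28 without KO adults 3, 33 without KO adults 2 and 34 without WT adults 2. They numbered 33 with DESeq2 and 38 with edgeR, with RLE or with TMM factors. Across genes, which are not independent replicates, the KO effects of the ages had Pearson's r = 0.457 and Spearman's rho = 0.391, from different libraries at each age, and r ranged from 0.174 (DESeq2) to 0.485 (deposited RPKM) over the alternatives. Srebf1, Areg, Ehhadh and Ppara rose at both ages, as did the xenobiotic receptor gene Nr1i2, from 110.0 ± 6.53 to 158.3 ± 11.2 CPM in neonates and from 111.0 ± 11.1 to 159.7 ± 12.3 CPM in adults. Susd2, Glb1, Lrat and Gip fell at both, Glb1 by -0.58 on the log2 scale at each age.

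**Figure D4:**
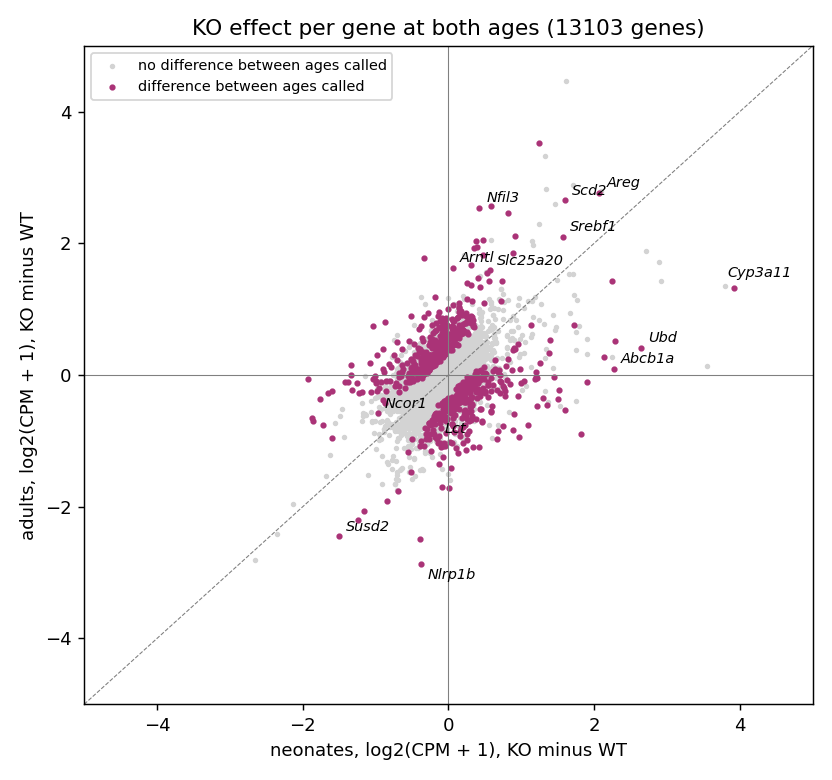
KO effect in neonates (x axis, log2 difference) against that in adults (y axis, log2 difference) for 13103 genes, 1 point per gene, coloured where the difference between ages was called. Genes such as Srebf1 and Areg lie high on both axes, and Abcb1a and Nlrp1b lie near a single axis.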

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

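In this part the tests of liver tissue and of scaling for the plasma protein genes, and the scan of windows over the genome, were chosen only after the result was seen.

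The KO effect differed between ages for 796 of 14588 genes by limma's test of the difference itself, and 68 genes named by the rule that passed it are given here as log2 KO effect in adults minus that in neonates (adjusted p up to 0.046). The rule named 186 genes in this test, part of them for a large change at a single age, which favours a difference. Differences are signed. A higher effect in adults can be a smaller fall, as for Gsta3, Dhcr7 and Ncor1, and a lower one a smaller rise, as for Cyp3a11. The effect was higher in adults for 35 of these: Lrp2 (2.91), Ces2b (2.29), Ryr1 (2.20), Tmprss6 (2.17), Serpina1e (2.16), Nfil3 (2.12), Nox4 (2.02), C8b (2.002), Acot1 (1.99), Igf2os, the Igf2as of the neonate table (1.99), Nr0b2 (1.66), Cyp3a44 (1.59), Arntl (1.57), Gsta3 (1.31), Sucnr1 (1.23), Gclc (1.20), Bmp8a (1.16), Gstm1 (1.07), Scd2 (1.06), Slc25a20 (1.02), Bhlhe40 (0.95), Lss (0.82), Npas2 (0.82), Insig1 (0.81), Fcgrt (0.81), Areg (0.69), Dhcr7 (0.64), Mcm2 (0.61), Cry2 (0.58), Srebf1 (0.53), Gclm (0.51), Slc51a (0.44), Rxra (0.42), Tbl1xr1 (0.40) and Ncor1 (0.39). It was lower in adults for 33 of them: Abcg5 (-0.37), Slc5a1 (-0.48), Tff3 (-0.54), Lrat (-0.60), Apoc3 (-0.66), Mgam (-0.73), Enpep (-0.76), Ugt2b34 (-0.80), Lct (-0.81), Defa24 (-0.82), Cyp3a25 (-0.82), Amn (-0.92), Slc2a2 (-0.94), Susd2 (-0.94), Slc15a1 (-0.96), Olfr165 (-0.96), Fras1 (-1.06), Pipox (-1.06), Serpinb5 (-1.58), Lrrc3 (-1.72), Sis (-1.75), Adh6a (-1.78), Cyp2c65 (-1.87), Ugt2b38 (-1.94), Ifit2 (-1.995), Akr1c14 (-2.10), Abcb1a (-2.18), Ubd (-2.23), Nlrp1b (-2.49), Cyp3a11 (-2.60), Plb1 (-2.68), Cyp2b10 (-2.72) and Hgd (-3.88). At about 1 CPM or below a fall is barely detectable, as for Lrp2, Nox4 and C8b in adults and Plb1, Serpinb5 and Ugt2b38 in neonates. Low levels of Nlrp1b in WT neonates, 1.29, 1.61 and 4.5 CPM, limited a fall there too. The libraries whose omission ends the call for Ces2b are WT neonates 1 (0.0749), WT neonates 2 (0.0817), WT adults 1 (0.0654), WT adults 3 (0.0514) and KO adults 3 (0.058).

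By list, camera's test of the difference called 13 lists. The effect was lower in adults for adult-type enterocyte genes (adjusted p = 1.47e-06), brush border (7.38e-10), phase I drug metabolism (1.47e-06), phase II conjugation (0.00718), efflux transporters (0.018), lipid absorption (0.0367), interferon response (3.94e-06) and Paneth cell genes (0.0339). It was higher in adults for PPAR-alpha targets (7.28e-09), circadian clock (0.0117), cholesterol synthesis (7.38e-10), oxidative stress response (0.000149) and the corepressor complex (0.018). With an estimated correlation camera called none of the 40 lists (6 at an unadjusted p under 0.05, adjusted p from 0.132 to 0.531 for these 13 lists), and fry called 7.

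Of 100 splits of the libraries within the ages, 2 gave 796 genes or more, the real split included, and the highest other gave 817, with the adults as they are and the neonates divided otherwise. Such splits remove the KO effect of an age and add it to the spread, so they bear on whether there is a KO effect, and not on whether it differs between ages. The difference in the number of genes rests on limma's test. For the 13 lists, 42 of 100 splits gave as many or more, the real split included. The highest other gave 24, with both ages divided otherwise. An added spread does not explain more called lists, so the number of called lists is no more than such splits give.

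Plasma protein genes, a list written after the values were seen that also holds the membrane protease gene Tmprss6, were mostly lower in KO neonates. By limma 10 of 14 fell and Ttr rose from 142.5 to 302.6 CPM. With TMM factors Serpina1b, at 14.8 CPM in WT and 18.3 CPM in KO, was called higher too (limma adjusted p = 0.0207). Of 26 members found, 14 passed the filter. It takes in a low gene above the minimum in WT alone, such as Serpina1d (3.13 and 0.443 CPM), which favours falls in this count. Liver tissue carried into WT libraries would bring albumin above Serpina1e. The ratio of Alb to Serpina1e in WT neonates was 0.0284 (0.0109 to 0.0579 in single libraries), which argues against liver as the source of Serpina1e. That ratio does not cover low members such as Alb itself, at 7.12 CPM in WT and 1.01 CPM in KO neonates. Scaling by the total does not account for the lower levels, since the median log2 difference with TMM factors was -1.38 (SD 0.939 over the 14 members). Lower expression in intestinal cells of KO neonates stays open, as a direct or an indirect effect of the loss of NCoR1. The cells that express these genes were not identified, and a change in the share of cell types was not tested for them.

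Nlrp1b had 8, 8 and 6 reads in KO adults and 111, 131 and 106 in WT adults, against 24, 7 and 6 in KO neonates and 11, 15 and 38 in WT neonates. A single library does not explain it, since the highest adjusted p of limma over the fits without 1 library was 2.85e-05. Nlrp1b lies within 10 megabases of Ncor1, where 12 of 247 tested genes (4.86%) changed at least 2-fold in adults against 0.991% elsewhere, a ratio of 4.9 (Fisher's exact p = 1.26e-05), so variants of another strain carried along with the altered Ncor1 locus are a candidate explanation. The 12 genes include Nlrp1b itself, and Fisher's test takes neighbouring genes as independent, so this ratio is weak evidence for that explanation. Of 1007 overlapping windows over the genome 4 (0.397%) held as high a share, 1 of them on chromosome 11. The highest share, 5.88%, was reached on a chromosome other than 11. The ratio was 1.08 in neonates (3 of 255 genes, Fisher's exact p = 0.759), and the window also holds Srebf1 and Slc22a5, lipid genes that may respond to NCoR1 itself, so strain and an effect of NCoR1 on Nlrp1b both remain open.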

How the results depend on the processing

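In this part the settings chosen only after the data were seen are limma and edgeR with TMM factors, deposited RPKM, and totals without Rn45s, Mir6236 and Lars2 or without the 50 most abundant genes.

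Scaling decides how many genes count as higher or lower. Genes higher and lower in KO neonates numbered 1278 and 1098 with TMM factors in limma, 1353 and 1044 with edgeR and TMM, and 1350 and 1043 with edgeR and RLE, and in KO adults 1334 and 854, 1251 and 905, and 1238 and 912. DESeq2 called 1526 genes in neonates (543 lower), and 1166 higher and 650 lower in adults. With deposited RPKM 437 were higher in neonates, and adults had 1167 calls with 386 lower. A minimum of 1.5-fold, stricter by construction, left 600 genes in neonates (194 higher, 406 lower), 719 in adults (254, 465) and 410 for the difference between ages (225, 185). With an estimated correlation camera called 6 lists in neonates, 0 in adults and 0 for the difference. For the other changes the cause was not tested. The remaining settings with all libraries kept each count of called genes within 1.5 times. Calls of the same sign with TMM factors numbered 1839 of 3009 in neonates, 1595 of 2611 in adults and 718 of 796 for the difference. The correlation of the KO effects between ages, 0.457, ranged from 0.174 (DESeq2) to 0.485 (deposited RPKM).

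Without 1 library, neonates had 2020 to 2581 calls (594 to 660 higher, 1426 to 1979 lower), adults 1281 to 2552 (437 to 732, 844 to 1840) and the difference 517 to 1047 (281 to 598, 226 to 449). Lists called numbered 13 to 17 in neonates, 13 to 20 in adults and 10 to 14 for the difference. Of 207 calls of named genes 52 ended without 1 library, and none reversed sign while called. With TMM factors 89 of 104 calls of named genes were kept in neonates and 88 of 93 in adults.

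The splits of 3 libraries against 3 are 10 per age, too few for a share under 0.05. As many genes came in 1 of 10 splits at each age, the real one, with 3009 real and 1 at most otherwise in neonates, and 2611 and 0 in adults. As many lists came in 4 of 10 splits in neonates (16 real, 19 at most otherwise) and 3 of 10 in adults (15 and 19). With the replicate number as a block limma called 3575 genes in neonates, 2272 in adults and 792 for the difference. The numbers were not taken to pair the libraries: WT and KO residuals of the same number correlated at 0.16, 0.14 and 0.029 in neonates and 0.062, -0.21 and -0.12 in adults, above the highest of other numbers for 3 of 6. KO neonates 3 had the lowest depth, which limits genes with few reads. Alternatives for the values of WT adults beside WT neonates, and for the KO effect along that difference, were not run except TMM factors for the latter, and 41 combinations of a named gene and a setting gave no value.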

Other observations

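In this part the tests of shared WT libraries and of fewer cells outside the epithelium, and the lists of imprinted genes, aldo-keto reductases and EGF ligands, were chosen only after the result was seen.

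Between WT adults and WT neonates, given as values only, Sis stood at 7638 and 31.9 CPM, Cyp2b10 at 444.3 and 0.622 CPM, and Fcgrt at 55.6 and 4664 CPM. Of the suckling-type enterocyte genes 11 of 12 were lower in each adult library than in each neonate library, and 7 of 7 adult-type genes, 10 of 12 brush border genes and 18 of 22 phase I genes were higher. Higher by the same measure were 14 of 14 Paneth and 14 of 18 cholesterol synthesis genes, and lower were 14 of 25 PPAR-alpha targets and 11 of 14 interferon genes.

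KO effects in neonates ran along this WT age difference over 14588 genes (r = 0.327). Those in adults had r = 0.0302 with it, but there the WT adults enter with opposite signs, which lowers r. No value without a KO effect was given for adults, so these correlations are not like measures. For neonates, the WT neonates enter both sides with the same sign, which raises r. The covariance of 0.109 lay above the highest of 100 simulations with unchanged KO neonates, 0.0135. This argues against independent noise per gene in the shared libraries as the whole cause. Variation that many genes share within a WT neonate pool was not simulated, so it stays open. With TMM factors the correlation was 0.321. Such factors shift the log2 differences of all genes nearly alike, which leaves a correlation over genes almost unchanged, so this value cannot test scaling. A smaller share of cells outside the epithelium stays open, since the median over their markers with TMM factors was -0.0813 with an SD of 0.228 (43 genes). Lower in each WT adult than each WT neonate library were 7 of 7 fibroblast, 6 of 6 endothelium and 8 of 8 neuron and glia genes. Of 8 myeloid genes 6 were lower and 1 higher, and of 8 smooth muscle genes 4 and 1. Of 8 B and plasma cell genes 0 were lower and 3 higher. An early shift of the epithelium of KO neonates toward adult expression may act for part of the genes, but in KO neonates 20 of 24 PPAR-alpha targets and 7 of 14 interferon genes rose, and 1 of 12 Paneth and 1 of 17 cholesterol synthesis genes (3 lower) were higher.

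Of 14 imprinted growth genes tested in neonates 6 were lower by limma, or 4 with TMM factors, and of 12 in adults 4, or 2 with TMM factors. Igf2 fell from 141.7 ± 36.5 to 44.3 ± 1.61 CPM in neonates (limma adjusted p = 0.00275) and from 8.04 ± 1.03 to 2.90 ± 0.256 CPM in adults (limma adjusted p = 0.000182). Of 10 aldo-keto reductase genes 4 were higher and 2 lower in neonates, or 5 higher and none lower with TMM factors. In adults 2 were higher and 2 lower, the same with TMM factors. Of 8 EGF ligand genes 2 were higher and 1 lower in neonates, or 2 and none with TMM factors, and 2 higher in adults. Besides Areg, Ereg was higher at both ages, at 5.95 ± 1.11 and 14.2 ± 0.662 CPM in neonates (limma adjusted p = 8.15e-06) and 16.7 ± 6.17 and 36.4 ± 5.64 CPM in adults (limma adjusted p = 0.0316), with an age difference of -0.02 (limma adjusted p = 0.987).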
